A study of Homo sapiens with 30 samples.

How the data were processed

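Gene expression was measured in a co-culture of Caco-2 and HT29-MTX cells. Caco-2 is a human colorectal carcinoma line that differentiates into cells resembling absorptive enterocytes, and HT29-MTX is a mucus-secreting line selected from human colon carcinoma cells with methotrexate. The lines were mixed at 75% and 25%, kept on porous Transwell inserts for 14 days, and then exposed on the apical side to multi-walled carbon nanotubes (MWCNT) or nanobelts of titanium dioxide (TiO2-NB) at 10 or 100 µg/ml for 1 or 24 h. Control wells were given fresh medium alone, and the labels name no particle-free suspension control. The 30 arrays form 10 groups of 3 biological replicates, 2 of them controls (1 h and 24 h), and each array was hybridised with labelled RNA copied from 3 µg of total RNA.

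The deposited values are log2 probe set levels, 1 per probe set and array, summarised by the authors with RMA, per the submitters' processing notes. RMA corrects the background, makes the distributions of all arrays alike (quantile normalisation) and summarises the probes of each probe set by median polish. The version of RMA and the chip definition file are not given in the sources used here. The values were taken as deposited, with no further scaling. Quantile normalisation removes differences in overall RNA amount, so each change below is relative to the other transcripts on the same arrays. The table holds 22277 probe sets on each of the 30 arrays; 62 control probe sets were left out of the tests and 22215 were tested. An array has no read depth, and the number of arrays per group limits the precision. Genes were named from the platform annotation paired with the table: 19064 tested probe sets carry 1 symbol, 1043 carry several and 2108 carry none, and names were taken only from those with 1. Of these, 19052 matched the RefSeq gene table by gene identifier, and 0 symbols changed. Where a gene has several probe sets, the one with the highest mean over all 30 arrays stands for it, which gives 11963 genes. No probe coordinates were available, so no genomic position is given.

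All tests were run in R 4.3.3 with limma 3.58.1. A mean per group was fitted to each probe set over all 30 arrays with lmFit, so that the 10 groups share 1 estimate of the spread (20 residual degrees of freedom, with 3.68 added by eBayes). Comparisons were made two-sided and adjusted by Benjamini-Hochberg over all probe sets within each comparison, and an adjusted p under 0.05 is a call. Each exposed group was compared with the control of its time, 100 with 10 µg/ml, MWCNT with TiO2-NB at the same dose and time, the effect of 100 µg/ml at 24 h with that at 1 h (interaction), and the controls of the 2 times with each other. A moderated F-test over the 4 exposed groups and the control was made at each time. In the text, ± is the standard error of the log2 change from limma, with n = 3 arrays per group, unless a standard deviation (SD) is named.

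The 29 gene lists hold 941 members, of which 797 were measured. Each was tested against the other genes with camera (preset inter-gene correlation 0.01), two-sided, with Benjamini-Hochberg adjustment over all lists and the 8 comparisons with control. Camera was repeated with a correlation estimated from the arrays, and fry, which asks whether the members of a list move one way on balance, was an alternative. Counts of list members are given over all probe sets tested and adjusted over the list alone. The probe sets that the array carries for 18S and 28S ribosomal RNA, and for the 5′ and 3′ ends of GAPDH and ACTB, served as signs of RNA quality and were compared by exact two-sided permutation tests. With 3 arrays against 3, the smallest exact p is 0.1.

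The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. For 100 µg/ml against control, the rule names up to 12 genes that rose and 12 that fell, by size of change, among called genes whose 3 exposed arrays all lie on the same side of the 3 controls. For 10 µg/ml it names 6 and 6, and for other comparisons 5 and 5, with no condition on the arrays for the interactions. Where fewer than 6 genes passed against control, the 6 with the smallest p are named as not having passed. In each list up to 4 members with the smallest p are named and, for oxidative stress, inflammation, metallothioneins and mucus, up to 4 with the highest level. Genes outside this rule are marked as chosen after their values were seen.

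The alternatives were a fit on the compared groups only, the replicate number as a block, a filter on the lowest 1 in 3 of probe sets by mean level, a second quantile normalisation, an intensity trend with robust variances, array weights, 1 probe set per gene, and leaving out each array in turn. For the gene lists, only arrays of the controls and of TiO2-NB at 100 µg/ml for 24 h were left out. The 18S level of each array as a covariate was added after the data were seen. So was a comparison of the exposures in pairs with separate control arrays, where shared calls were set against the number expected for independent lists within 20 groups of probe sets of like variance. The steps were tested on simulated data built from the real means and variances. With 100 probe sets changed 1.5-fold and 100 changed 2-fold among 22215, the simulated comparison of MWCNT at 100 µg/ml for 24 h recovered 96% and 100%, with 9 false calls, and that of TiO2-NB at 100 µg/ml for 1 h recovered 94% and 100%, with 6 false calls. A simulated list of 30 genes shifted by 0.1 log2 among 11963 genes was called in the first of these, and 0 of 20 unchanged lists were called. The noise of each gene was drawn independently, so the simulation could not show false list calls that arise from correlated genes.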

Results

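The data are log2 expression levels of 22215 tested probe sets on 30 arrays, 3 biological replicates in each of 10 groups. At 1 h and at 24 h there was a control given fresh medium, and there were groups exposed to MWCNT or TiO2-NB at 10 or 100 µg/ml. The array medians lay between 6.45 and 6.49, and the lowest correlation between arrays of the same group was 0.997. Each gene named for the size of its change against control had its 3 exposed arrays on the same side of all 3 controls.

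The first question was what the cells do within 1 h of meeting MWCNT. FAM13A, which carries a RhoGAP domain, fell by 1.16 ± 0.089 on the log2 scale at 10 µg/ml, a 2.23-fold change (n = 3 arrays per group, adjusted p = 3.24e-08). It fell by 1.04 ± 0.089 at 100 µg/ml, or 2.06-fold (adjusted p = 1.39e-07). PCK1, the enzyme that commits carbon to gluconeogenesis, fell by 1.11 ± 0.13 and by 0.95 ± 0.13, and KANK1, a regulator of actin at cell adhesions, fell by 0.90 ± 0.065 and by 0.85 ± 0.065. The largest rises were those of DDIT4, a stress-induced inhibitor of mTORC1, by 0.96 ± 0.11 and 1.08 ± 0.11, and of BHLHE40, a transcription factor of hypoxia and the clock, by 0.85 ± 0.11 and 1.04 ± 0.11.

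Further genes were named by the rule. Rises at 10 µg/ml were found for EOGT (0.79 ± 0.10), PHF14 (0.71 ± 0.15), the ubiquitin ligase RNF111 (0.62 ± 0.054) and the helicase MCM9 (0.62 ± 0.085), and falls for the natriuretic peptide NPPB (-0.91 ± 0.11), the MYC antagonist MXI1 (-0.85 ± 0.084) and the immediate early factor EGR1 (-0.84 ± 0.12). The glutathione-degrading enzyme CHAC1 rose at 100 µg/ml by 0.71 ± 0.13, the p53 target TIGAR by 0.60 ± 0.068, LRP1 by 0.59 ± 0.12 and AHR, the receptor for dioxins and related ligands, by 0.55 ± 0.059. The nuclear receptors RARB (-0.86 ± 0.092) and PPARG (-0.74 ± 0.064) fell, as did KHDC4 (-0.75 ± 0.081), GRAMD2B (-0.73 ± 0.071) and SIRT4 (-0.60 ± 0.10).

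With MWCNT at 10 µg/ml, 1435 probe sets were called, 569 up and 866 down, 35 of them changed at least 1.5-fold. There were 1729 at 100 µg/ml, 780 up and 949 down, 34 of them at least 1.5-fold. The probe set for 18S ribosomal RNA stood above the control by 1.17 at 10 and by 1.51 at 100 µg/ml, and that for 28S by 0.47 and 0.65 (exact permutation p = 0.1 for each, the smallest that 3 arrays against 3 allow). With the 18S level as a covariate, an alternative chosen after seeing the data, 698 and 347 probe sets were called, and with the compared groups alone 84 and 112. The count was, at 10 µg/ml, 758 without control replicate 2 and 710 without MWCNT replicate 1, and at 100 µg/ml it was 1112 without MWCNT replicate 3.

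**Figure D1:**
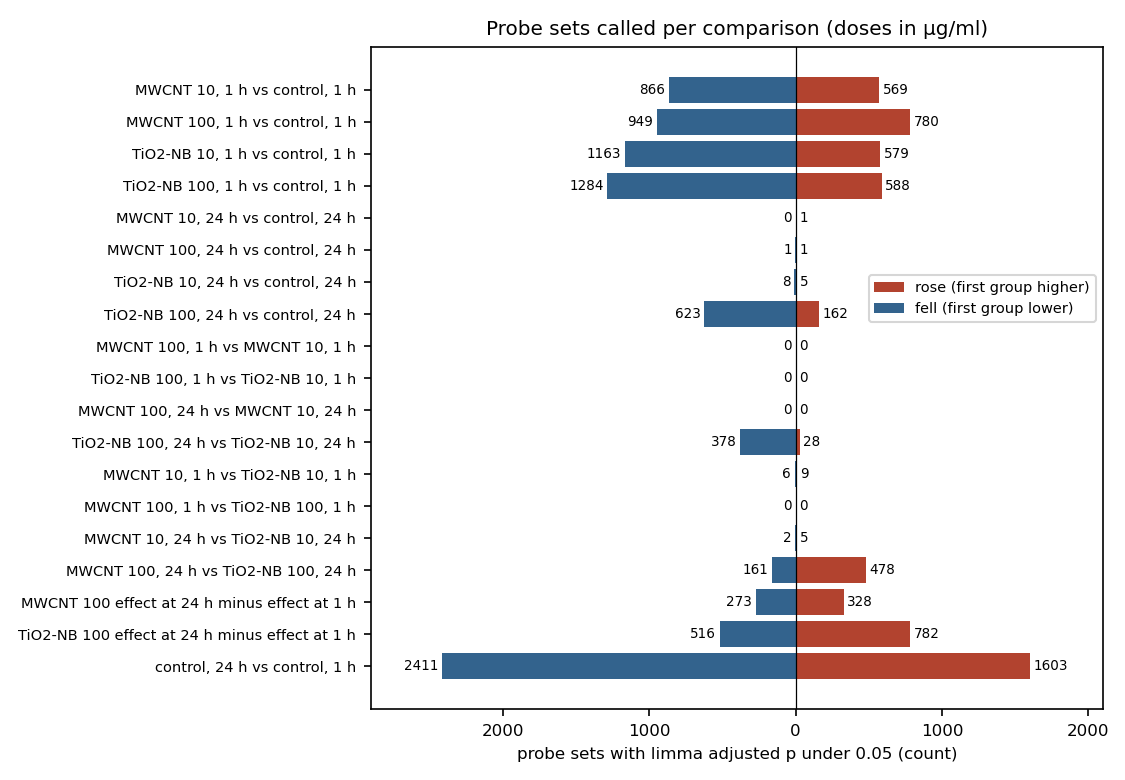
Number of probe sets called by limma (x axis, risen to the right of 0 and fallen to the left) in each of the 19 comparisons (y axis), as bars. The 4 comparisons with control at 1 h each hold between 1435 and 1872 calls; at 24 h TiO2-NB at 100 µg/ml holds 785 and the other exposures between 1 and 13.

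Among the gene lists at 1 h of MWCNT, the list of NF-kB and inflammatory genes was lower as a whole at both doses. With an estimated correlation the call held at 100 µg/ml (adjusted p = 0.0458) and ended at 10 µg/ml (adjusted p = 0.0716), and the 18S probe set was higher in both groups, by 1.51 and 1.17. NFKBIA, which holds NF-kB in the cytoplasm, fell by 0.60 ± 0.054 at 10 and by 0.61 ± 0.054 at 100 µg/ml. TNFAIP3, a ubiquitin-editing enzyme that ends NF-kB signalling, fell by 0.56 ± 0.048 and by 0.59 ± 0.048. The neutrophil attractant CXCL8 fell by 0.81 ± 0.15 at 10 µg/ml, the chemokine CCL20 by 0.28 ± 0.085 and by 0.34 ± 0.085, while the NF-kB subunit RELB rose by 0.36 ± 0.080 and 0.37 ± 0.080. Of 32 measured members 1 rose and 6 fell at 10 µg/ml, and 25 did not pass (adjusted over the list alone, 1 and 8; camera adjusted p = 0.0113). In the 100 µg/ml group 1 rose, 7 fell and 24 did not pass (list alone 1 and 9; camera adjusted p = 0.00539).

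The 9 genes listed as aryl hydrocarbon receptor targets, not all of them genes of foreign-compound metabolism, were higher as a list at both MWCNT doses. Of these 2 rose and 7 did not pass at 10 µg/ml (adjusted over the list alone, 3 rose; adjusted p = 0.0486, and adjusted p = 0.206 with an estimated correlation). With 100 µg/ml 4 rose, 1 fell and 4 did not pass (list alone 4 and 1; adjusted p = 0.0222, and adjusted p = 0.125 with an estimated correlation). The members that rose at 10 µg/ml were AHR itself and NFE2L2, the master regulator of antioxidant genes (0.20 ± 0.046 and 0.25 ± 0.046 at the 2 doses), and at 100 µg/ml CYP1A2 and the amino acid transporter SLC7A5 rose too. TIPARP, a repressor of the receptor and 1 of its classical targets, was the member that fell at 100 µg/ml (-0.17 ± 0.053), and CYP1A1 did not pass (0.15 ± 0.11 and -0.095 ± 0.11); both were chosen after their values were seen. The call at 10 µg/ml ended without control replicate 2 (adjusted p = 0.0621) or control replicate 3 (adjusted p = 0.069). The 18S probe set moved with this list, by 1.17 and 1.51.

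Ribosome biogenesis and junction genes were also higher, and mitotic genes lower, with MWCNT at 1 h. No call of this paragraph held with an estimated correlation. In the same groups 18S stood above the control by 1.17 and 1.51 and 28S by 0.47 and 0.65. Of 31 ribosome biogenesis genes 6 rose and 1 fell at 10 µg/ml and 8 rose and 1 fell at 100 µg/ml, among them RRS1 (0.35 and 0.36) and DDX21 (0.25 and 0.36), with 24 and 22 not passing (list alone 8 and 2, then 10 and 1; adjusted p = 0.00455 and 0.00257, and adjusted p = 0.383 and 0.343 with an estimated correlation). Of 25 tight and adherens junction genes 2 rose and 1 fell at 10 µg/ml, and 5 rose at 100 µg/ml, among them TJP1, the scaffold of the tight junction (0.31 and 0.34). There, 22 and 20 did not pass (list alone 5 and 1, then 7 and 0; adjusted p = 0.032 and 0.0109, and adjusted p = 0.722 and 0.653 with an estimated correlation). Of 35 mitotic genes 10 fell at 10 µg/ml, and 6 fell and 1 rose at 100 µg/ml, with AURKA (-0.24 and -0.25) and KIF20A (-0.35 and -0.28) among the falls. There, 25 and 28 did not pass (list alone 1 and 16, then 1 and 9; adjusted p = 4.77e-04 and 0.0231, and adjusted p = 0.722 and 0.863 with an estimated correlation). Of 29 hypoxia and glycolysis genes 6 fell at 10 µg/ml and 1 rose, with 22 not passing (list alone 9 and 1; adjusted p = 0.0112, and adjusted p = 0.863 with an estimated correlation), and 4 of 63 genes of oxidative phosphorylation fell, with 59 not passing (list alone 10 fell and 1 rose; adjusted p = 0.0021, and adjusted p = 0.838 with an estimated correlation). The hypoxia call ended without control replicate 2 (adjusted p = 0.243), and the junction call at 10 µg/ml without control replicate 1 (adjusted p = 0.104) or 3 (adjusted p = 0.0804). The mitotic call at 100 µg/ml ended without control replicate 1 (adjusted p = 0.104) or 3 (adjusted p = 0.273).

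The same question was put for TiO2-NB at 1 h, and FAM13A again fell most at both doses. It fell by 1.47 ± 0.089 at 10 µg/ml, 2.76-fold (adjusted p = 4.18e-10), and by 1.33 ± 0.089 at 100 µg/ml, 2.52-fold (adjusted p = 1.58e-09). PCK1 fell by 1.06 ± 0.13 and by 0.96 ± 0.13, and KANK1 by 1.03 ± 0.065 and by 1.01 ± 0.065. BHLHE40 rose by 1.04 ± 0.11 and 1.26 ± 0.11, or 2.05-fold and 2.40-fold, and DDIT4 by 0.86 ± 0.11 and 1.15 ± 0.11. There were also rises at 10 µg/ml of TIGAR (0.59 ± 0.068), RNF111 (0.51 ± 0.054), DUSP6, a phosphatase that restrains ERK (0.51 ± 0.093), and ZNF239 (0.48 ± 0.061), and falls of KHDC4 (-0.98 ± 0.081), CXCL8 (-0.89 ± 0.15) and EGR1 (-0.84 ± 0.12). DUSP6 rose at 100 µg/ml by 0.60 ± 0.093, CHAC1 by 0.59 ± 0.13, EREG, a ligand of the EGF receptor, by 0.56 ± 0.11, and the lipase LIPG by 0.54 ± 0.076. RARB (-1.02 ± 0.092), PPARG (-0.88 ± 0.064), ZKSCAN1 (-0.83 ± 0.16), SLA (-0.79 ± 0.079), MXI1 (-0.78 ± 0.084) and N4BP2L1 (-0.70 ± 0.096) fell.

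With TiO2-NB at 10 µg/ml, 1742 probe sets were called, 579 up and 1163 down, 44 of them changed at least 1.5-fold. There were 1872 at 100 µg/ml, 588 up and 1284 down, 55 of them at least 1.5-fold. The 18S probe set stood above the control by 0.84 (exact permutation p = 0.4) and 0.80 (exact p = 0.1), and the 28S probe set by 0.44 (exact p = 0.2) and 0.34 (exact p = 0.1). With the compared groups alone 219 and 269 probe sets were called. The lower dose's count was 1026 without control replicate 2, 1161 without control replicate 3 and 1136 without TiO2-NB replicate 3, and the higher dose's was 1234 without control replicate 3 and 1175 without TiO2-NB replicate 2.

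**Figure D2:**
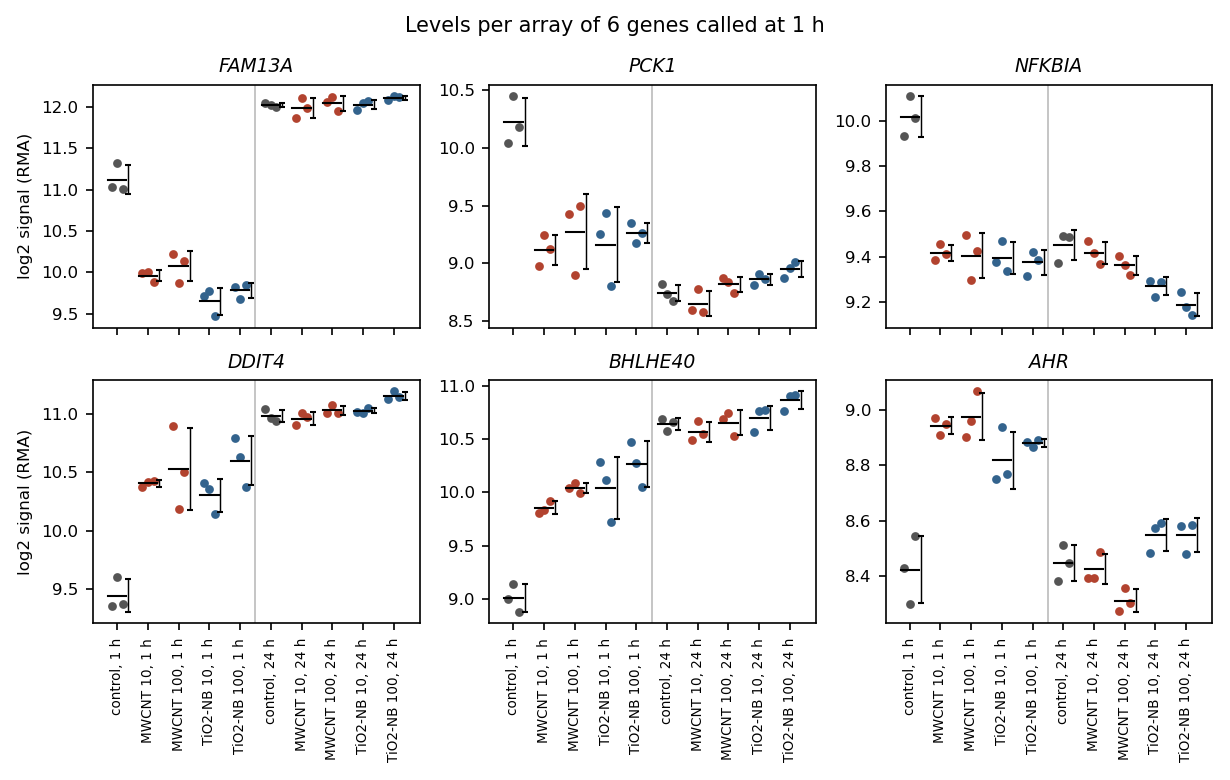
Log2 signal (y axis) of FAM13A, PCK1, NFKBIA, DDIT4, BHLHE40 and AHR in all 10 groups (x axis); points are the 3 arrays, lines the mean and error bars the SD. At 1 h all 4 exposed groups lie on the same side of the control for each of the 6 genes, with FAM13A between -1.04 and -1.47 from it.

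The TiO2-NB groups of 1 h share their 3 control arrays with the MWCNT groups, so list calls that recur are not independent. The list of aryl hydrocarbon receptor targets was higher with TiO2-NB too. At 10 µg/ml 4 of 9 rose and 5 did not pass (adjusted over the list alone, 5 rose; adjusted p = 0.00128), and at 100 µg/ml 5 rose and 4 did not pass (list alone 5; adjusted p = 8.69e-04), and both calls held with an estimated correlation (adjusted p = 0.0458 each). The risen members included AHR (0.40 and 0.46), NFE2L2 (0.19 and 0.23), CYP1A2 (0.21 and 0.30) and SLC7A5 (0.21 and 0.27), and, chosen after its values were seen, CYP1A1 at 100 µg/ml (0.43 ± 0.11, adjusted p = 0.0116). Of 32 inflammatory genes 3 fell and 1 rose at 10 µg/ml, with NFKBIA at -0.62 ± 0.054, TNFAIP3 at -0.50 ± 0.048 and RELB at 0.36 ± 0.080. There, 28 did not pass (list alone 3 and 1; adjusted p = 0.032, and adjusted p = 0.112 with an estimated correlation), and the call ended without control replicate 1 (adjusted p = 0.051) or 2 (adjusted p = 0.0621). The list was not called at 100 µg/ml, although NFKBIA fell by 0.64 ± 0.054, TNFAIP3 by 0.53 ± 0.048 and CXCL8 by 0.58 ± 0.15. The 18S probe set moved with these lists, by 0.84 and 0.80.

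Genes of the actin cytoskeleton were higher with TiO2-NB at 1 h, in groups where 18S stood above the control by 0.84 and 0.80. Of 32, 2 rose and 30 did not pass at 10 µg/ml (list alone 2; adjusted p = 0.0325, and adjusted p = 0.32 with an estimated correlation), and 4 rose and 28 did not pass at 100 µg/ml (list alone 7; adjusted p = 8.69e-04, and adjusted p = 0.0751 with an estimated correlation), with the crosslinker ACTN4 at 0.22 and the focal adhesion protein ZYX at 0.22. Ribosome biogenesis was higher at both doses, with 5 up and 1 down at 10 µg/ml and 6 up and 2 down at 100 µg/ml of 31, among them RRS1 (0.34 and 0.36), and 25 and 23 not passing (list alone 11 and 2, then 6 and 3; adjusted p = 0.00261 and 0.0486, and adjusted p = 0.343 and 0.705 with an estimated correlation). Hypoxia and glycolysis genes were lower at 10 µg/ml, where 8 of 29 fell and 2 rose, with 19 not passing (list alone 12 and 2; adjusted p = 8.69e-04, and adjusted p = 0.838 with an estimated correlation). They included KDM3A, a histone demethylase (-0.59), and EGLN1, the oxygen sensor that marks HIF for degradation (-0.54), while DDIT4 of the same list rose. DNA replication was higher at 10 µg/ml, with 3 of 37 up and 34 not passing (list alone 4; adjusted p = 0.00455, and adjusted p = 0.863 with an estimated correlation). Calls ended for actin at 10 µg/ml without control replicate 3 (adjusted p = 0.0692), for ribosome biogenesis at 100 µg/ml without control replicate 2 (adjusted p = 0.181) and for DNA replication without control replicate 2 (adjusted p = 0.422).

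At 100 µg/ml TiO2-NB further lists were called that were not called at 10 µg/ml, a difference that was not tested, and 18S was higher there by 0.80. Of 35 mitotic genes 7 fell and 28 did not pass, with KIF20A at -0.31 and HMMR at -0.29 (list alone 7; adjusted p = 0.0051, and adjusted p = 0.838 with an estimated correlation). Of 18 heat shock genes 3 fell and 15 did not pass: the co-chaperone CHORDC1 (-0.41), HSPA1L (-0.33) and HSPH1 (-0.25) (list alone 6 fell and 1 rose; adjusted p = 0.0486, and adjusted p = 0.206 with an estimated correlation). Of 63 genes of oxidative phosphorylation 4 fell and 59 did not pass (list alone 2; adjusted p = 0.00388, and adjusted p = 0.838 with an estimated correlation). Markers of macrophages and other leukocytes, cells that the culture does not hold, were higher, with 3 of 23 up and 20 not passing (list alone 5; adjusted p = 0.034, and adjusted p = 0.416 with an estimated correlation). The lysozyme gene LYZ, also on the list of enteroendocrine and Paneth cells, rose by 0.28, NKG7 by 0.22 and CD53 by 0.26. Without control replicate 3 the mitotic (adjusted p = 0.0954), heat shock (adjusted p = 0.0962) and leukocyte (adjusted p = 0.153) calls ended, the last also without control replicate 1 (adjusted p = 0.0565).

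**Figure D3:**
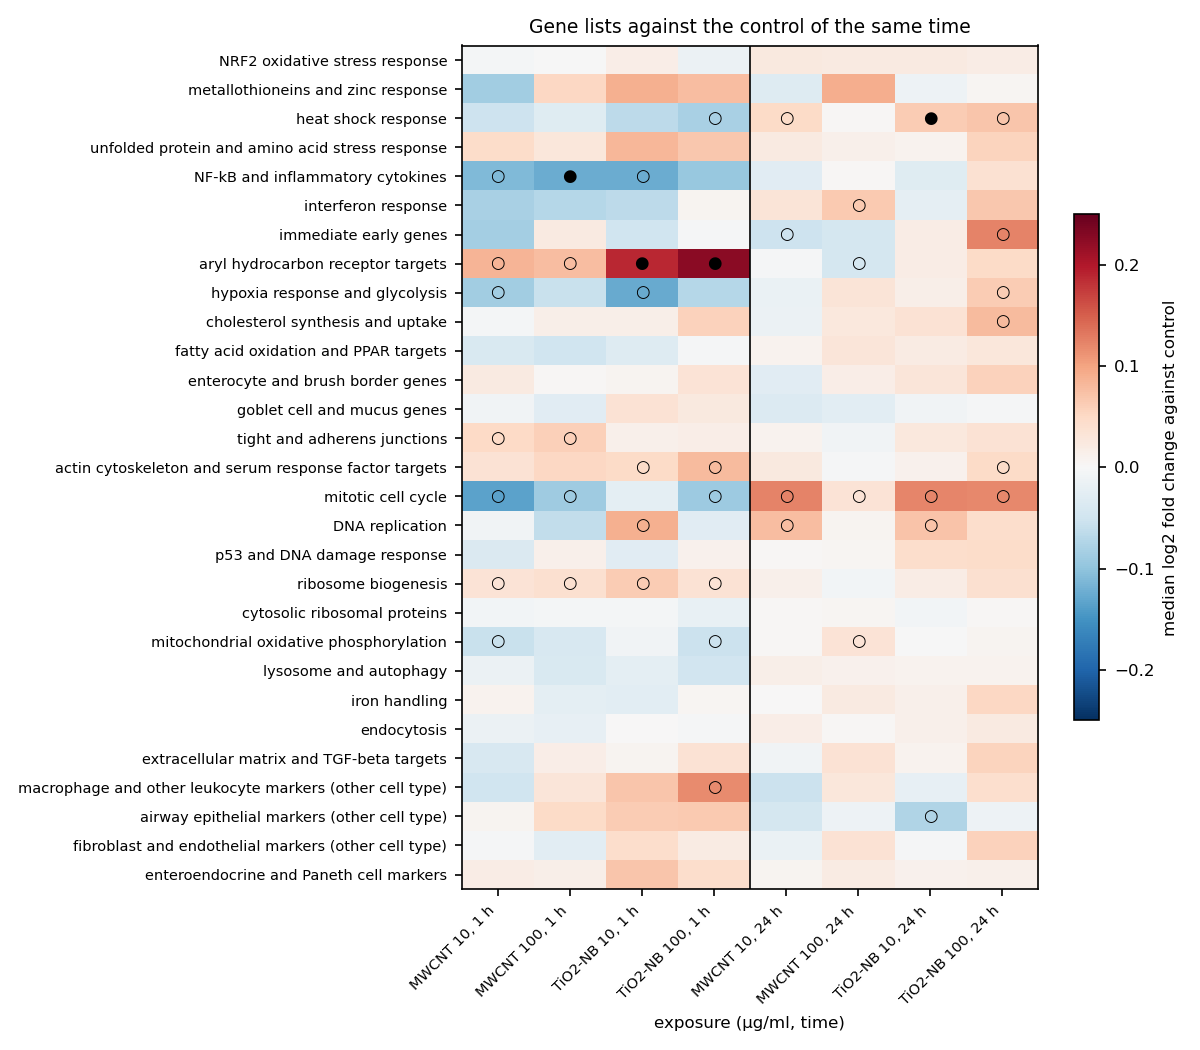
Median log2 change (colour, scale ended at 0.25 either way) of the measured members of 29 gene lists (y axis) in the 8 comparisons with control (x axis). Open circles mark camera calls at the preset correlation, 43 in all, and filled circles the 4 that also hold with an estimated correlation.

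How alike the exposures were at 1 h was asked across all genes and by shared calls. In all 4 exposed groups 201 probe sets rose and 408 fell, which stand for 134 and 298 genes, and FAM13A, PCK1, KANK1, DDIT4, BHLHE40, NFKBIA and TNFAIP3 were among them. The log2 changes of any 2 exposed groups correlated at r = 0.68 to 0.81 over 11963 genes, where genes are not independent replicates. The groups share 1 set of 3 control arrays, and simulated arrays with no effect gave a mean r of 0.50 and a highest value of 0.526 for that reason. Some pairs at 24 h lay farther below that mean, so the simulated spread may be narrower than that of the arrays. No count expected without effects is given for the calls shared by all 4 groups, since 3 controls cannot be split 4 ways. The covariance of the changes exceeded the simulated one by 0.00914 to 0.0124. In a test chosen after the data were seen, 1 control array served 1 group of a pair and the other 2 served its partner, in 6 ways per pair, so that r is expected at 0 without effects. There r lay between 0.27 and 0.56. Between TiO2-NB at 10 and 100 µg/ml, 71 to 111 probe sets then rose in both, against at most 9.85 for independent lists among probe sets of like variance, and 141 to 372 fell in both, against at most 44.3. Between MWCNT and TiO2-NB at 100 µg/ml, 98 to 133 rose in both, against at most 16.2, and 91 to 283 fell in both, against at most 36.3. Up to 5 probe sets of a pair were called in opposite directions there, and 0 with the shared controls.

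The F-test over the 4 exposed groups and the control called 1892 probe sets at 1 h. Among the 4 exposed groups alone, 4 differed there, with 2847 at an unadjusted p under 0.05. The count was 1143 without control replicate 2 and 1153 without control replicate 3, and 590 with the arrays of 1 h alone.

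Whether more particles gave a larger response at 1 h was tested by 100 against 10 µg/ml. For FAM13A the values stood side by side at -1.16 and -1.04 with MWCNT and at -1.47 and -1.33 with TiO2-NB, and for DDIT4 at 0.96 and 1.08 and at 0.86 and 1.15. In limma 0 probe sets were called for either particle, with 1518 for MWCNT and 1427 for TiO2-NB at an unadjusted p under 0.05. Without MWCNT 100 µg/ml replicate 2 the count for MWCNT was 2.

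The particles were compared with each other at 1 h. At 10 µg/ml, the zinc finger genes ZNF623 (0.45 ± 0.077), ZBTB6 (0.35 ± 0.062) and ZNF302 (0.31), the secernin SCRN3 (0.32) and FOXD1 (0.24) were higher with MWCNT. NPPB (-0.57 ± 0.11), the bombesin receptor GRPR (-0.33) and NENF (-0.23) were lower with it. There were 15 calls, 9 higher and 6 lower with MWCNT, with 3041 at an unadjusted p under 0.05 and 18.7% of probe sets not overlapping between the groups, where chance gives 10%. The count was 0 without MWCNT replicate 1, 2 without replicate 2, 1 without replicate 3, 0 without TiO2-NB replicate 1 and 1 without replicate 3. It was 0 with the compared groups alone, 27 without the dimmest probe sets, 8 after a second quantile normalisation, 35 with an intensity trend and 94 with array weights. At 100 µg/ml limma called 0, with 2055 at an unadjusted p under 0.05 and 12.9% not overlapping, and 1 without MWCNT replicate 1 or 2. The median 95% interval of a difference reached 0.158 to either side, and the largest difference of any tested probe set was 0.67 at 10 and 0.78 at 100 µg/ml.

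After 24 h of MWCNT, the largest change among the genes called was that of CYP1A1, the monooxygenase most strongly induced through the aryl hydrocarbon receptor. At 100 µg/ml it fell by 1.04 ± 0.11, or 2.06-fold, from a mean of 7.36 to 6.31 (n = 3, adjusted p = 1.68e-05). At 10 µg/ml it stood at -0.57 ± 0.11 and did not pass (adjusted p = 0.122). A probe set of the phosphatase PTP4A1, chosen after its values were seen, rose at both doses, by 0.53 ± 0.059 and 0.41 ± 0.059, and also with TiO2-NB, by 0.40 ± 0.059 and 0.32 ± 0.059, against the same 3 controls. The brightest probe set of PTP4A1 stood at 0.02 and -0.11 with MWCNT and was not called. These were all the calls, 1 at 10 and 2 at 100 µg/ml, with 952 and 1236 at an unadjusted p under 0.05. Others of the smallest p did not pass: the splicing kinase CLK1 (0.32 ± 0.067, adjusted p = 0.273), PODXL (0.23) and MSMB (0.35) at 10 µg/ml, and TDG (-0.25, adjusted p = 0.249), KCNE2 (-0.35, adjusted p = 0.249) and PAGE4 (0.74 ± 0.17, adjusted p = 0.414) at 100 µg/ml. With the compared groups alone the counts were 0 and 0, and with 1 probe set per gene 0 and 1. The count at 10 µg/ml was 2 without the dimmest probe sets, 3 with an intensity trend and 5 with array weights, and that at 100 µg/ml was 1 without MWCNT replicate 3.

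Mitotic genes were higher as a list at 24 h with MWCNT. At 10 µg/ml all 35 lay above 0, with a median of 0.12, although 0 rose by limma over all probe sets or adjusted over the list alone (adjusted p = 1.17e-16, and adjusted p = 0.147 with an estimated correlation). DNA replication (34 of 37 above 0; adjusted p = 2.65e-04, and adjusted p = 0.838 with an estimated correlation) and heat shock (adjusted p = 0.0155, and adjusted p = 0.112 with an estimated correlation) were higher too, and immediate early genes lower (adjusted p = 0.0222, and adjusted p = 0.838 with an estimated correlation), again with 0 members passing by either adjustment. The last call ended without control replicate 1 (adjusted p = 0.0602) or 2 (adjusted p = 0.0582).

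At 100 µg/ml the mitotic list was higher with 0 members passing (adjusted p = 0.0486, and adjusted p = 0.863 with an estimated correlation), a call that ended without control replicate 1 (adjusted p = 0.111) or 3 (adjusted p = 0.391). Oxidative phosphorylation was higher, with 57 of 63 above 0 (adjusted p = 4.69e-06, and adjusted p = 0.588 with an estimated correlation), as were 32 interferon genes (adjusted p = 0.0021, and adjusted p = 0.416 with an estimated correlation), with 0 members of either passing by either adjustment. The 9 aryl hydrocarbon receptor targets were lower, but CYP1A1 was the 1 member that fell, over all probe sets and over the list alone, and 8 did not pass (adjusted p = 0.0067, and adjusted p = 0.0751 with an estimated correlation).

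With TiO2-NB at 10 µg/ml for 24 h, 6 genes passed. CLK1, a kinase of the SR splicing factors, rose by 0.70 ± 0.067 (n = 3, adjusted p = 4.31e-06), and DMXL2 rose by 0.37 ± 0.072. The chromatin regulator ANKRD11 (-0.85 ± 0.14), the glucosylceramide synthase UGCG (-0.79 ± 0.12), the phosphatase and actin regulator PHACTR2 (-0.68 ± 0.13) and LINC00339 (-0.50 ± 0.071) fell. In probe sets chosen after their values were seen, the splicing factor SRSF6 fell by 0.70 ± 0.092, and a probe set of the topoisomerase TOP1 was called as falling. There were 13 calls, 5 up and 8 down, with 1686 at an unadjusted p under 0.05. The count was 8 without control replicate 3, and 5 with 1 probe set per gene.

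Heat shock genes were higher as a list at 10 µg/ml TiO2-NB, with 16 of 18 above 0 and 0 passing by either adjustment (adjusted p = 0.00174, and adjusted p = 0.0458 with an estimated correlation). Mitotic genes were higher, with 33 of 35 above 0, a median of 0.12, 0 passing over all probe sets and 1 over the list alone (adjusted p = 2.32e-12, and adjusted p = 0.235 with an estimated correlation). DNA replication was higher (adjusted p = 8.69e-04, and adjusted p = 0.838 with an estimated correlation), and 12 airway epithelial markers, which stand for a cell type the culture does not hold, were lower (adjusted p = 0.0158, and adjusted p = 0.229 with an estimated correlation), with 0 members of either passing by either adjustment. The airway call ended without control replicate 3 (camera adjusted p = 0.0539). In this TiO2-NB group 18S stood above the control by 0.40 and 28S by 0.17 (exact permutation p = 0.2 for each).

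TiO2-NB at 100 µg/ml for 24 h gave the broadest change of that time, and it was mostly a fall. The receptor of interleukin 6, IL6R, fell by 1.75 ± 0.18 on the log2 scale, 3.35-fold (n = 3, adjusted p = 5.19e-07). PHACTR2 fell by 1.73 ± 0.13, or 3.31-fold, MBP by 1.76 ± 0.17, the zinc finger gene ZNF12 by 1.59 ± 0.17, PLPP3, which dephosphorylates lipid signals, by 1.53 ± 0.16, and PLEKHA1 by 1.52 ± 0.15. WASL, an activator of actin branching, fell by 1.52 ± 0.22, the forkhead factor FOXO3 by 1.51 ± 0.16, KLF13 by 1.50 ± 0.18, NAA15 by 1.45 ± 0.25, MTDH by 1.45 ± 0.15 and ANKRD11 by 1.45 ± 0.14. Fewer genes rose, led by the peptide hormone UTS2 (0.93 ± 0.26, adjusted p = 0.0403), CLK1 (0.88 ± 0.067, adjusted p = 1.16e-08) and CCL20, which attracts dendritic cells and lymphocytes (0.80 ± 0.085, adjusted p = 8.57e-07). Then came CST1 (0.55 ± 0.13), the neuropeptide galanin GAL (0.49 ± 0.067), PDGFRA (0.49 ± 0.13), the proapoptotic PMAIP1 (0.45 ± 0.12), SPRY2, a brake on receptor tyrosine kinases (0.45 ± 0.063), the cytokine signalling inhibitor SOCS2 (0.44 ± 0.12), EREG (0.43 ± 0.11) and ARL14 (0.41 ± 0.10).

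In this comparison 785 probe sets were called, 162 up and 623 down, and of the 299 that changed at least 1.5-fold 5 rose and 294 fell. Of the fallen probe sets, 297 have a brighter probe set of their gene, and the median change was -0.63 for the fallen and 0.01 for the brighter, while for 50 of the 297 the brighter probe set was called as falling too. For TPR, chosen after its values were seen, they were -2.55 and 0.01. A further 275 fallen probe sets, those of the fallen genes named above among them, are the brightest of their gene. These were not compared with dimmer probe sets of the same gene. The count was 491 without TiO2-NB replicate 3, 217 with the compared groups alone, 376 with 1 probe set per gene and 1381 with array weights. Of the calls with array weights 37.1% had risen, against 20.6% of the 785.

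**Figure D4:**
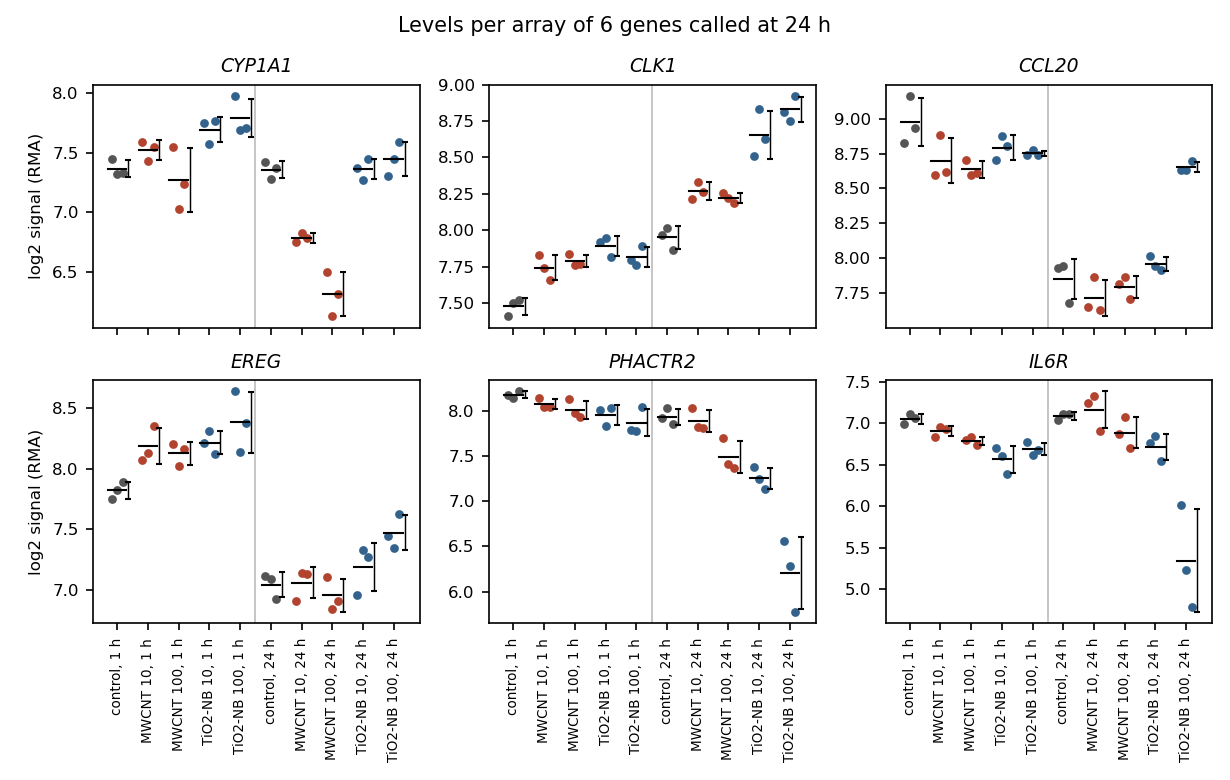
Log2 signal (y axis) of CYP1A1, CLK1, CCL20, EREG, PHACTR2 and IL6R in all 10 groups (x axis); points are the 3 arrays, lines the mean and error bars the SD. CYP1A1 is lower at 24 h with MWCNT, and PHACTR2 and IL6R are lower with TiO2-NB at 100 µg/ml, by 1.04, 1.73 and 1.75.

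**Figure D5:**
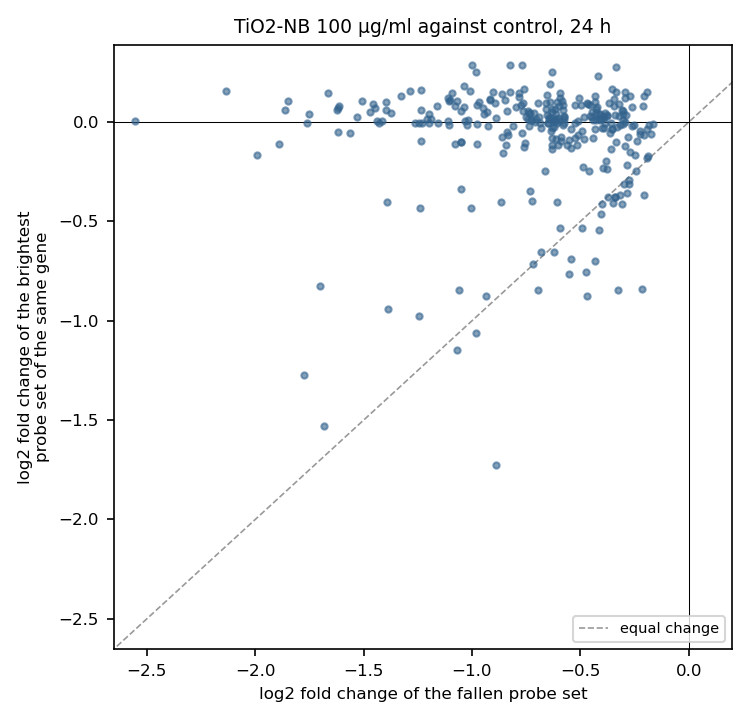
Log2 change of the brightest probe set of a gene (y axis) against that of its fallen probe set (x axis) for TiO2-NB at 100 µg/ml and 24 h, 1 point for each of the 297 pairs; the dashed line marks equal change. Most points lie near 0 on the y axis, with a median of 0.01.

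Immediate early genes, the first wave of transcription after a stimulus, were higher as a list at 100 µg/ml TiO2-NB. Of 34, 5 rose, 1 fell and 28 did not pass, with PHLDA1 at 0.35 and KLF6, the 1 that fell, at -0.88 ± 0.17 (list alone 9 and 1; adjusted p = 0.00128, and adjusted p = 0.642 with an estimated correlation). Hypoxia and glycolysis genes were higher, with 28 of 29 above 0 and the glucose transporter SLC2A1 (0.28 ± 0.057) the 1 that rose (list alone 6; adjusted p = 8.69e-04, and adjusted p = 0.838 with an estimated correlation). Of 32 actin genes 2 rose and 30 did not pass (list alone 4; adjusted p = 0.00235, and adjusted p = 0.114 with an estimated correlation), and all 35 mitotic genes lay above 0, with a median of 0.12 and 0 passing by either adjustment (adjusted p = 3.96e-07, and adjusted p = 0.465 with an estimated correlation). Heat shock (adjusted p = 0.0435, and adjusted p = 0.205 with an estimated correlation) and cholesterol synthesis (adjusted p = 0.0191, and adjusted p = 0.838 with an estimated correlation) were higher with 0 members passing by either adjustment. The heat shock call ended without control replicate 1 (adjusted p = 0.0765) or 2 (adjusted p = 0.0558) or TiO2-NB replicate 1 (adjusted p = 0.108) or 3 (adjusted p = 0.0717), and the cholesterol call without TiO2-NB replicate 2 (adjusted p = 0.0965).

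Outside the called lists, the gel-forming mucin MUC5AC rose by 0.33 ± 0.084 and the vitamin B12 receptor gene CUBN fell by 0.56 ± 0.12 at 100 µg/ml TiO2-NB for 24 h. The leukocyte markers CD14 (0.31 ± 0.082) and CD37 (0.26 ± 0.073) rose, and NFKBIA fell by 0.26 ± 0.054. The aldo-keto reductases AKR1C1 (-0.18 ± 0.046) and AKR1C2 (-0.17) fell; they are targets of NRF2, the antioxidant regulator.

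The dose comparison at 24 h was called in many genes for TiO2-NB. From 10 to 100 µg/ml TiO2-NB, CCL20 (0.70 ± 0.085), SLC17A3 (0.37 ± 0.091), INPP5D (0.32 ± 0.085) and GAL (0.32 ± 0.067) rose. IL6R (-1.38 ± 0.18), ZNF12 (-1.19 ± 0.17), MCM3AP-AS1 (-1.17 ± 0.24), WASL (-1.12 ± 0.22) and PLPP3 (-1.10 ± 0.16) fell. There were 406 calls, 28 up and 378 down, 169 of them at least 1.5-fold. The count was 266 without TiO2-NB 10 µg/ml replicate 2, 191 without TiO2-NB 100 µg/ml replicate 3, 190 with 1 probe set per gene and 2 with the compared groups alone. Between the MWCNT doses limma called 0, with 1478 at an unadjusted p under 0.05.

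The particles were also set against each other at 24 h. At 100 µg/ml IL6R (1.54 ± 0.18), WASL (1.35), MBP (1.34), NAA15 (1.34) and PLEKHA1 (1.31) were higher with MWCNT than with TiO2-NB. CYP1A1 (-1.13 ± 0.11), CCL20 (-0.86 ± 0.085), CLK1 (-0.61 ± 0.067), the adhesion antigen CEACAM5 (-0.52 ± 0.074) and EREG (-0.52 ± 0.11) were lower. There were 639 calls, 478 higher and 161 lower with MWCNT. The count was 416 without MWCNT replicate 2, 351 without TiO2-NB replicate 3, 8 with the compared groups alone, 338 with 1 probe set per gene and 1045 with array weights.

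At 10 µg/ml UGCG (0.84 ± 0.12), SBNO1 (0.49 ± 0.089) and LINC00339 (0.39) were higher with MWCNT, and CYP1A1 (-0.58 ± 0.11) and CLK1 (-0.38 ± 0.067) lower. There were 7 calls. The count was 2, 2 and 4 without MWCNT replicates 1, 2 and 3, and 3 and 2 without TiO2-NB replicates 2 and 3. The F-test at 24 h called 698 probe sets over the exposed groups and control and 698 among the 4 exposed groups alone. The former was 428 without TiO2-NB 100 µg/ml replicate 3, 1107 with array weights and 333 with 1 probe set per gene. The log2 changes of any 2 exposed groups correlated at r = 0.25 to 0.60 over genes, which are not independent replicates. With the shared controls, simulated arrays with no effect gave a mean of 0.50 and a highest value of 0.526. Of the 6 pairs, 4 lay below that mean, at r = 0.25 to 0.46. These lay farther from it than the highest simulated value, so the simulated spread may be narrower than that of the arrays. A value above the highest simulated one is thus not taken as a shared response by itself. Above the highest value lay TiO2-NB at 10 with TiO2-NB at 100 µg/ml (r = 0.60) and MWCNT with TiO2-NB at 10 µg/ml (r = 0.54). The covariance exceeded the simulated mean by 0.00462 and 0.000857 for these pairs and by 0.00235 for the particles at 100 µg/ml, where the highest simulated covariance was 0.00337 and the measured ones 0.0077, 0.00394 and 0.00543. With separate controls r lay between 0.27 and 0.39 for the TiO2-NB doses, between 0.082 and 0.19 for the particles at 10 µg/ml, between 0.16 and 0.23 for them at 100 µg/ml, and between -0.074 and 0.17 for the other 3 pairs. The TiO2-NB doses shared all 13 calls of the lower one with the shared controls, 5 up and 8 down. With separate controls 1 to 3 probe sets rose in both, against at most 0.0126 for independent lists, and 0 to 6 fell in both, against at most 0.239.

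Whether the effect at 100 µg/ml changed between 1 and 24 h was tested as an interaction. With MWCNT the effects on FAM13A (1.06 ± 0.13) and PCK1 (1.02 ± 0.19) were more positive at 24 h than at 1 h, as was that on OLR1 (0.91 ± 0.21). Those on DDIT4 (-1.03 ± 0.16), BHLHE40 (-1.02 ± 0.15) and CYP1A1 (-0.95 ± 0.15) were more negative. With TiO2-NB the differences were 1.42 ± 0.13 for FAM13A, 1.17 ± 0.19 for PCK1, 1.08 ± 0.090 for PPARG and 1.03 ± 0.12 for CCL20, and -1.69 ± 0.25 for KLF13, -1.57 ± 0.31 for WASL and -1.47 ± 0.24 for ZNF12. There were 601 calls for MWCNT and 1298 for TiO2-NB. For MWCNT the count was 375 without the 1 h MWCNT replicate 3, 335 and 362 without 24 h control replicates 2 and 3, 334 and 385 without the 24 h MWCNT replicates 1 and 3, 955 without the dimmest probe sets, 212 with the 18S covariate chosen after seeing the data, and 267 with the compared groups alone. For TiO2-NB it was 848 without the 24 h TiO2-NB replicate 3 and 748 with the compared groups alone.

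Between the controls of 1 and 24 h, more probe sets were called than in any comparison of exposed with control cells. HILPDA, a lipid droplet protein induced by hypoxia, rose by 2.07 ± 0.099 on the log2 scale, 4.20-fold, TMCC1 by 2.06 ± 0.10, RNF186 by 1.72 ± 0.15, BHLHE40 by 1.64 ± 0.11 and DDIT4 by 1.54 ± 0.11. The immediate early EGR1 fell by 2.55 ± 0.12, or 5.84-fold, RHOB by 1.57 ± 0.12, the stress factor ATF3 by 1.56 ± 0.14, CXCL8 by 1.48 ± 0.15 and PCK1 by 1.48 ± 0.13. There were 4014 calls, 1603 up and 2411 down, 222 of them at least 1.5-fold, and 2525 with the compared groups alone.

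Lists tied to particle toxicity that were not called in any of the 8 comparisons with control include the NRF2 response to oxidative stress. Of its 24 members SQSTM1, an autophagy receptor, rose in all 4 groups of 1 h (0.19, 0.24, 0.24 and 0.29), and SLC7A11, the cystine transporter, in 3 of them (0.27, 0.52 and 0.46). The abundant members FTL (-0.01), PRDX1 (-0.01) and TXN (-0.01) did not pass with MWCNT at 100 µg/ml for 1 h, and the smallest adjusted p of the list was 0.059. For 9 metallothionein and zinc genes it was 0.0589; MT2A, which binds metal ions, fell by 0.23 ± 0.061 with MWCNT at 10 µg/ml for 1 h. For 29 goblet cell and mucus genes it was 0.131, with the membrane mucin MUC13 up by 0.23, 0.20, 0.17 and 0.23 at 1 h. The smallest adjusted p was 0.182 for the unfolded protein response, 0.11 for fatty acid oxidation, 0.234 for enterocyte genes, 0.161 for p53 targets, 0.333 for ribosomal proteins, 0.234 for lysosomes, 0.333 for iron handling, 0.389 for endocytosis, 0.265 for fibroblast and endothelial markers, 0.199 for enteroendocrine and Paneth cells and 0.265 for the extracellular matrix.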

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

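The tests of the dose, of brighter probe sets and of a single aberrant array were chosen after the results were seen. So were the fit with the 18S level as a covariate and the allowance for time in the test of the 1 h controls. For 18S carry-over, the 1 h controls and the aryl hydrocarbon receptor targets, the bounds were written before the values of the tests. The patterns that these 3 tests address were, however, themselves results of these data. The test of other splits was not chosen after the results were seen. The effect of 100 µg/ml differed between 24 h and 1 h in 601 probe sets for MWCNT and in 1298 for TiO2-NB, by the interaction test. The arrays of each interaction were split anew into exposed and control within each time, in 100 splits with the real one, the others drawn at random. Of these, 1, the real one, gave as many calls, and the highest of the others were 377 and 647. Such splits break up the effect at 1 h as well as that at 24 h. At a share of 0.05 they speak against no effect at both times, but cannot tell whether the effects of the 2 times differ by chance. The MWCNT count was 375 without the 1 h MWCNT replicate 3, 335 and 362 without 24 h control replicates 2 and 3, and 334 and 385 without the 24 h MWCNT replicates 1 and 3; the TiO2-NB count was 848 without the 24 h TiO2-NB replicate 3. The ribosomal RNA probe sets lie outside the tested genes and were above all 3 controls at 1 h in all 3 arrays of these groups: 18S by 1.17 with MWCNT at 10 µg/ml, by 1.51 at 100 µg/ml and by 0.80 with TiO2-NB at 100 µg/ml, and 28S by 0.47, 0.65 and 0.34.

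The first pattern is the change of 609 probe sets shared by all 4 exposed groups at 1 h. For 18S carry-over as its whole cause, a regression over the 12 exposed arrays puts the shift at the control's 18S level at 0.328 (95% bounds 0.303 and 0.353). That is near the mean shift of 0.326 and above the bound of 0.163 set before. Across these arrays the shift did not track 18S (Pearson r = -0.0728, permutation p = 0.823, Spearman rho = 0, permutation p = 1, and r = -0.0419 without the 2 farthest arrays). The 609 were chosen, however, as called in all 4 groups on these same arrays. Such a choice favours a shift that is even over arrays of unlike 18S, so the regression cannot decide the question. Whether carry-over took part stays open. With 18S as a covariate, MWCNT calls dropped to 698 and 347, where the median log2 change of the original calls was 0.984 and 0.905 of its former size and the standard error 1.26 and 1.40 times as large, so those calls ended mostly through the wider error. Whether the 1 h controls stand apart stays open: the 24 h control lay on average at -0.412, -0.232 and -0.266 of the exposed arrays' shift, under the bound set before, but that bound made no allowance for time, which alone may account for the 4014 calls between the controls, 52.7% of the 609 among them, 115 in the direction of the exposed arrays (DDIT4 by 1.54, BHLHE40 by 1.64, PCK1 by -1.48) and 206 in the opposite one. Whether the response grows with dose stays open. Over probe sets called for the other particle, the shift at 100 µg/ml was 1.02 to 1.10 times that at 10 µg/ml for MWCNT. For TiO2-NB it was 1.12 to 1.24 times. Of these ratios only the highest, 1.24, lay above the bound set for them, and the others lay below it. A particle response, or the handling of wells given a suspension, may underlie the change, and the labels name no particle-free suspension control.

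The second pattern is the fall of probe sets with TiO2-NB at 100 µg/ml for 24 h. Against loss of the whole transcript, for the 297 fallen probe sets with a brighter probe set of their gene the brighter one moved by -0.0118 of the fallen one's median change (quartiles of the ratio -0.101 and 0.179), although 50 of the brighter ones were called as falling too, and 275 have no brighter probe set and are not covered. The 5′ minus 3′ difference moved by 0.0246 for ACTB and by -0.00503 for GAPDH (exact permutation p = 0.7 for each), from which no verdict on degraded RNA is drawn, so degradation stays open. Against a single aberrant array, 95.6% of the probe sets that fell without replicate 1 lay in replicate 1 below the mean of the 6 MWCNT arrays of 24 h, whose means took no part in choosing them, against 50.0% of all probe sets, although the fall was graded: its median from the control mean was -0.31, -0.62 and -0.90 in replicates 1, 2 and 3, each left out in turn, with 900, 616 and 491 calls. A candidate explanation that also stays open is altered processing of these transcripts, in introns or 3′ ends; it was not tested, since the probe positions are not at hand.

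The third pattern is the lower CYP1A1 with MWCNT at 24 h, at -0.57 and -1.04. Against lower expression across the aryl hydrocarbon receptor targets, the median of the other 8 members was 0.0062 at 10 µg/ml and -0.0297 at 100 µg/ml (camera, a test over genes; unadjusted p = 0.718 and 0.122). That list holds AHR and NFE2L2, which are not targets alone, and 8 members are few. A change of CYP1A1 alone, by its promoter or its messenger's stability, may be at work and was not tested.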

How the results depend on the processing

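The fit with the 18S level as a covariate was chosen after seeing the data; the other alternatives were planned. The causes of the differences were not tested. A fit on the compared groups alone has fewer residual degrees of freedom. It called 84 and 112 probe sets for MWCNT at 10 and 100 µg/ml at 1 h and 219 and 269 for TiO2-NB; at 24 h it called 0 and 0 for MWCNT and 217 for TiO2-NB at 100 µg/ml. It called 2 for the TiO2-NB doses at 24 h, 0 between the particles at 10 µg/ml and 1 h, 8 between them at 100 µg/ml and 24 h, 267 and 748 for the interactions of MWCNT and TiO2-NB, 2525 for the controls over time and 590 for the F-test at 1 h. With 18S, the calls were 698 and 347 for MWCNT at 10 and 100 µg/ml at 1 h and 212 for its interaction, and 1336, 1464 and 1147 for TiO2-NB. They shared 575, 309 and 172 calls in direction with the reported ones for MWCNT, and 6 of the original calls at 100 µg/ml changed sign.

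Leaving out the dimmest 1 in 3 of probe sets also lowers the number of tests. It gave 2 calls for MWCNT at 10 µg/ml and 24 h and 955 for the MWCNT interaction. Between the particles it gave 27 at 10 µg/ml and 1 h and 1 at 100 µg/ml and 1 h. The mean r of the exposures at 1 h was 0.798 with this filter, against 0.744. With 1 probe set per gene, fewer probe sets were tested. The calls at 24 h were then 0, 1, 5 and 376 for MWCNT at 10 and 100 and TiO2-NB at 10 and 100 µg/ml. There were 190 for the TiO2-NB doses at 24 h and 333 for the F-test at 24 h. Between the particles at 100 µg/ml there was 1 at 1 h, and there were 338 at 24 h. Array weights gave 5 for MWCNT at 10 µg/ml and 24 h, 1381 for TiO2-NB at 100 µg/ml and 24 h, 94 and 1045 between the particles at 10 µg/ml and 1 h and at 100 µg/ml and 24 h, and 1107 for the F-test at 24 h, and moved the share of risen calls of TiO2-NB at 100 µg/ml and 24 h from 20.6% to 37.1%. An intensity trend with robust variances gave 3 for MWCNT at 10 µg/ml and 24 h, and 35 and 1 between the particles at 10 and 100 µg/ml and 1 h. A second quantile normalisation gave 8 between the particles at 10 µg/ml and 1 h, moved the share of risen calls at 1 h from 39.7% to 48.6% and from 45.1% to 48.5% for MWCNT at 10 and 100 µg/ml and from 33.2% to 42.4% and from 31.4% to 43.0% for TiO2-NB, and moved no median of all probe sets by as much as 0.1. The replicate number as a block gave 2 and 4 calls for MWCNT at 10 and 100 µg/ml and 24 h, 3 between the particles at 100 µg/ml and 1 h, and 12 at 10 µg/ml and 24 h. The numbers do not pair the arrays: over 135 pairs of the same number the deviations correlated at a median r of 0.00802 (-0.279 to 0.209), and 12 of 30 arrays were closest to their own number.

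Without 1 array in turn, the counts ranged from 710 to 1221 and from 1112 to 1683 for MWCNT at 10 and 100 µg/ml at 1 h, and from 1026 to 1730 and 1175 to 1829 for TiO2-NB. At 24 h they ranged from 1 to 3 for MWCNT at 100 µg/ml, and from 8 to 18 and 491 to 900 for TiO2-NB at 10 and 100 µg/ml. The dose counts ranged from 0 to 2 for MWCNT at 1 h and from 191 to 574 for TiO2-NB at 24 h, and those between the particles from 0 to 12 and 0 to 1 at 1 h and from 2 to 9 and 351 to 685 at 24 h, for 10 and 100 µg/ml. The interactions ranged from 334 to 630 and 848 to 1472 for MWCNT and TiO2-NB, and the F-tests from 1143 to 2144 at 1 h and 428 to 721 at 24 h. Fewer arrays may explain part of the drops. The controls over time stayed between 2998 and 3490, and MWCNT at 10 µg/ml and 24 h had 1 call each time.

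Of 43 list calls 4 held with an estimated correlation. With fry 24 lists were called, 19 of them among the 43; the block kept 42, the filter 34 and the arrays of the same time alone 36, and no direction reversed. Named genes lost their call in 164 instances without 1 array, gained it in 2 and counted as unchanged in 1016. With array weights these were 3, 1 and 173, with the block 1, 1 and 175, and with the filter 0, 0 and 161. A gene not called in the reported fit counted as unchanged also where its direction changed. Of the named genes that were called, none reversed. The 3 arrays per group limit all of these, and dim probe sets near the array background can show smaller changes than the transcripts have.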

Other observations

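The list results below for the controls over time and for the doses were chosen after the data were seen, as was the comparison of the shared genes with the controls. Between 1 and 24 h immediate early genes and several stress lists were lower in the controls. Of 34 immediate early genes 21 fell and 1 rose, with EGR1 at -2.55 ± 0.12 and KLF10 at -0.76 (adjusted over the list alone, 23 and 1; adjusted p = 5.58e-12, and adjusted p = 0.181 with an estimated correlation). Of 24 genes of the unfolded protein and amino acid stress response 12 fell and 1 rose, with the chaperone HSPA5 at -0.21 and its partner SDF2L1 at -0.45 (list alone 13 and 1; adjusted p = 1.59e-04, and adjusted p = 0.287 with an estimated correlation). Of 24 p53 genes 12 fell and 4 rose, with TIGAR at -0.96, GADD45A at -0.74, SESN1 at 0.55 and APAF1 at 0.68 (list alone 13 and 5; adjusted p = 0.00876, and adjusted p = 0.554 with an estimated correlation). NF-kB genes were lower, with 9 down and 2 up of 32, among them CCL20 (-1.13 ± 0.085), NFKBIA (-0.57) and TNFAIP3 (-0.46) (list alone 9 and 2; adjusted p = 0.00885, and adjusted p = 0.101 with an estimated correlation), and 5 of 9 metallothionein genes fell, MT1X by 0.50 and MT2A by 0.33 (list alone 5; adjusted p = 0.0176, and adjusted p = 0.554 with an estimated correlation). Ribosome biogenesis, with 11 down and 1 up of 31 (list alone 14 and 1; adjusted p = 8.38e-04, and adjusted p = 0.392 with an estimated correlation), and oxidative phosphorylation, with 14 down and 1 up of 63 (list alone 17 and 1; adjusted p = 5.76e-04, and adjusted p = 0.724 with an estimated correlation), were lower as well. Not all stress genes fell: of 18 heat shock genes, 5 rose and 2 fell, with CHORDC1 at 0.66, DNAJB4 at 0.60 and HSPH1 at 0.43 (list alone 5 and 4), and the list was not called (adjusted p = 0.419, and adjusted p = 0.725 with an estimated correlation).

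Hypoxia and mitotic genes were higher in the 24 h control. Of 29 hypoxia and glycolysis genes 8 rose and 0 fell, with adrenomedullin ADM at 0.89, the glycolytic switch PFKFB3 at 0.63 and KDM3A at 0.62 (list alone 10; adjusted p = 6.88e-05, and adjusted p = 0.725 with an estimated correlation). Of 35 mitotic genes 5 rose, with TOP2A at 0.35 and CDK1 at 0.22 (list alone 5; adjusted p = 0.0176, and adjusted p = 0.849 with an estimated correlation). Of the 609 probe sets shared by the 4 exposures at 1 h, 39.4% moved in the direction of the controls over time, 115 were called there in the same direction and 206 in the opposite one. Both changes are taken from the same controls of 1 h, which ties their directions together even without effects. The share expected for that reason was not computed. Metallothioneins were lower at 10 than at 100 µg/ml MWCNT at 1 h, with 0 passing and 3 over the list alone (adjusted p = 6.70e-04, and adjusted p = 0.287 with an estimated correlation). The mean log2 levels in control, 10 and 100 µg/ml were 8.52, 8.29 and 8.49 for MT2A and 7.62, 7.39 and 7.67 for MT1X, so for these the 10 µg/ml group lay below the control and the 100 µg/ml group near it. At 24 h too the list was lower at 10 than at 100 µg/ml, with 0 passing and 2 over the list alone. Camera gave an adjusted p of 0.0046, and of 0.429 with an estimated correlation. The levels of 24 h in control, 10 and 100 µg/ml were 7.13, 7.13 and 7.33 for MT1X and 8.14, 8.10 and 8.29 for MT1F. For these the 10 µg/ml group lay near the control and the 100 µg/ml group above it, unlike at 1 h. The list was not called against control at either dose or time. Between the particles at 100 µg/ml and 24 h, immediate early genes were lower with MWCNT, with 5 down and 1 up (list alone 16 and 1; adjusted p = 2.30e-06, and adjusted p = 0.413 with an estimated correlation).

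Other splits of the arrays into groups of the same sizes were counted for each comparison. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Against control at 1 h the real split called 1435, 1729, 1742 and 1872 (MWCNT at 10 and 100, TiO2-NB at 10 and 100 µg/ml), and the highest of the others 2, 3, 1 and 2. At 24 h these were 1, 2, 13 and 785 against 0 in each. For the doses they were 0 and 0 at 1 h against 0 and 2, and 0 and 406 at 24 h against 1 and 8, for MWCNT and TiO2-NB. Between the particles they were 15 and 0 at 1 h against 0 and 1, and 7 and 639 at 24 h against 1 and 1, for 10 and 100 µg/ml, and for the controls over time 4014 against 0. The number of splits with as many calls, the real one included, was 1, except for the comparisons with a real count of 0, where it was 10. For the F-tests, 1 of 100 splits, the real one, gave as many calls at each time, 1892 against at most 1153 at 1 h and 698 against at most 553 at 24 h. These splits mixed all arrays of a time. At a share of 0.05 they speak against no difference among any of the exposed groups and the control of that time. They cannot tell which groups differ, and at 24 h the F-test among the 4 exposed groups alone also called 698.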
